A study of Malassezia pachydermatis with 2 samples.

How the data were processed

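RNA was sequenced from 2 strains of Malassezia pachydermatis, with 1 library for the ketoconazole-sensitive CBS 1879 and 1 for the ketoconazole-resistant KCTC 27587. Per the labels' protocols, libraries were made from 1 µg of total RNA with a stranded Illumina kit for total RNA after 3 days on agar and 6 h in broth at 34 °C. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.35, Bowtie2 2.2.4, featureCounts and edgeR, with no role, order or genome build. Whether counting used strand is not given in the sources used here.

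The values analysed are the TPM of each gene, its read count per coding length scaled to a fixed library total, in each strain as deposited by the authors, on gene models of the resistant strain. The deposited table also holds the authors' ratio (fold) of the TPM columns, resistant over sensitive. It equalled the quotient of the TPM columns in all 4106 genes that have one, within a relative 1e-06, and was not used further. The other 10 genes are listed at 0 in the sensitive strain. Positions of genes and exons come from the deposited annotation of KCTC 27587, predicted with AUGUSTUS per the file content, on 6 chromosomes. The name of that assembly is not given in the sources used here. Gene identifiers of table and annotation were matched by their number. Exons held almost only coding sequence, so lengths are coding lengths. Products are those of the table: 1255 of 4116 genes (30.5%) are hypothetical or uncharacterized, and 1074 products carry a CBS 1879 locus tag, all of which were found among 4202 genes of the CBS 1879 reference table, assembly GCF_001278385.1. No gene model overlapped an earlier one. In 186 places neighbouring genes share a named product, and these can be parts of 1 gene.

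Each TPM column sums to 1000000. TPM times coding length fell on whole multiples of 1 step per library, which gave the reads behind each gene. Among values under 1000 reads and precise enough to tell, 100% of 1151 values in the sensitive and 100% of 922 in the resistant library lay within 0.1 of a whole read, against 21.9% and 21.0% when lengths were shifted by 1 gene, which also checked the match of identifiers. The recovered totals were 8742866 and 9683100 assigned reads. They served for depth, for exact (Clopper-Pearson, conditional) 95% intervals of a ratio, and for a floor of 3 reads per library where a gene is listed at 0. The reads carry no molecular identifiers, so intervals and floors cover counting error only. The floor is the one-sided 95% limit of a count of 0, so a ratio to it lies above the lower bound of the two-sided interval. At the 5% quantile a gene had 117 reads in the sensitive and 161 in the resistant library.

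With 1 library per strain no test was made. Before the data were examined, the following were fixed: the log2 ratio of TPM with a pseudocount of 1; genes with TPM of at least 1 in either strain (all 4116 passed); counts of genes at least 2-fold and at least 4-fold apart; medians by chromosome; and raised or lowered runs, where the rolling median over 11 neighbouring genes lies at least 1 from the median of all genes, set beside 10000 random gene orders. Lists of genes were also fixed: ergosterol pathway, sterol regulators, drug efflux, heat shock and chaperones, oxidative stress, cytosolic and mitochondrial ribosomal proteins, secreted hydrolases, cell wall, glycolysis, respiratory chain and ATP synthase, beta-oxidation and peroxisome, iron and copper uptake, proteasome and housekeeping controls. Members were matched by the words of their product. A list of rRNA, tRNA and mitochondrially encoded genes had no member in the annotation used here. The median of a list of at least 3 members was placed among 10000 random lists of the same size matched on deciles of mean expression, as a description of these libraries.

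Named genes followed a rule fixed beforehand, for genes with a named product: all ergosterol and sterol regulator genes; the 10 highest and 10 lowest log2 ratios at TPM of at least 10 in either strain; in the longest run the 8 genes with the highest TPM in the resistant strain and the first and last gene; and of each other list the 4 members with the largest differences at that TPM, of which the text gives most. The cytochrome P450 genes and single genes said to be so were chosen after their values were seen.

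Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at TPM 10, median-of-ratios scaling, rescaling without the top 1% of genes or without the longest run, windows of 7 and 21 genes, a run threshold of 0.58, list members outside the run, and list members matched by symbol. Steps were also run on simulated data. Of 200 genes planted at 4 fold sizes among the 4116, 200 came out within 1.5-fold of the planted ratio, and the edges of 100 planted blocks of 51 genes raised 4-fold were each found within 6 genes in 100. The planted size equals that of the block found in the data, whose median ratio of 2.80 is under the planted 4-fold. The recovery therefore does not carry over to the weaker edges of that block. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.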

Results

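Total RNA was sequenced from 2 strains of Malassezia pachydermatis, a lipophilic yeast that lives on the skin of dogs and other animals. CBS 1879 was sensitive to ketoconazole, an azole that blocks ergosterol synthesis at lanosterol 14-alpha-demethylase, and KCTC 27587 was resistant to it. Each strain grew for 3 days on mDixon agar and then for 6 h in mDixon broth at 34 °C, and neither label records drug in the culture. There was 1 library per strain, so no difference below has a replicate check, and no test or p-value was possible. Each value is the deposited TPM of a gene in the sensitive strain followed by that in the resistant strain, and each log2 ratio is that of TPM + 1, resistant over sensitive, which understates the ratio of low genes. The TPM values of 4116 genes came from 8742866 assigned reads in the sensitive library and 9683100 in the resistant one, with medians of 870.5 and 986 reads per gene. Intervals of a ratio are exact 95% intervals from these reads, cover counting error only, and say nothing of the spread between cultures.

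Across the genome 85.6% of the genes were less than 2-fold apart between the strains. Among genes with a named product, a thioredoxin-like protein (MP87_01272, chromosome 2, 774,728 to 775,484) was at TPM 8.03 in the sensitive strain and 774 in the resistant one, the highest log2 ratio of TPM + 1 (6.42) and a TPM ratio of 96.4 (interval 73.4 to 129). A spermine transporter (MP87_03195) was listed at 0 against 60.1, at least 289.5-fold higher when the sensitive strain is set to a floor of 3 reads. The general amino acid permease agp2 (MP87_00488) was at 0 against 58.5 and a carboxylic acid transporter (MP87_00563) at 0 against 37.6, at least 122-fold and at least 178-fold higher. Since the gene models are those of the resistant strain, genes near 0 in the sensitive strain may also be absent from it or diverged there. In the other direction, a P-loop nucleoside triphosphate hydrolase (MP87_00409, chromosome 1, 837,357 to 839,210) was at 2629.5 against 11, which is 239-fold lower in the resistant strain (interval 209 to 275).

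The other highest ratios among named genes were those of a ferric reductase (MP87_02944, log2 ratio 5.53), a zf-DHHC domain protein (MP87_00562, 5.21), a secretory lipase of family 3 (MP87_01267, 5.19), a metabolite transporter (MP87_03790, 4.86), a chitin deacetylase (MP87_03762, 4.66) and an exo-beta-glucanase (MP87_00884, 4.66). MP87_00562 rested on 1 read in the sensitive library, and its TPM ratio of 396 had an interval from 68.8 to 15266. All of these genes but the chitin deacetylase were below TPM 1 in the sensitive strain, so the limit on genes near 0 applies. The lower genes in the resistant strain included a secretory lipase of family LIP (MP87_03766, 221 against 12.2), a family 3 lipase (MP87_00002, 39.4 against 2.69), a dynein regulator (MP87_01870, log2 ratio -2.59), a family 2 glycosyltransferase (MP87_01440, -2.49) and a DNA glycosylase (MP87_00372, -2.32). A neighbouring P-loop hydrolase (MP87_00410, -2.28), an aldo-keto reductase (MP87_00040, -2.15), a GPR/FUN34 family protein (MP87_02893, -2.08) and a WD40 exocytosis protein (MP87_01657, -2.05) completed the 10 named genes with the lowest ratios. Of the 4116 genes, 393 were at least 2-fold higher and 201 at least 2-fold lower in the resistant strain, and 113 and 20 differed by at least 4-fold. The median log2 ratio was -0.07, with quartiles of -0.44 and 0.40. Across genes, log2(TPM + 1) correlated with Pearson's r = 0.885 and Spearman's rho = 0.875, which describes these libraries, since genes are not independent replicates.

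The series title names a tandem quadruplication in the genome, so the ratio was followed along the chromosomes. A single long block stood out, on chromosome 4 from 907,643 to 991,273 in the deposited KCTC 27587 annotation, with 51 neighbouring genes over 83.6 kb. It holds genes for iron reduction, sterol synthesis, a cytochrome P450, copper transport and mitochondrial translation. Its median log2 ratio was 1.48, a median ratio of 2.80 with quartiles of 2.15 and 4.0, and 43 of its genes were at least 2-fold higher in the resistant strain, 8 were under 2-fold apart and 0 were at least 2-fold lower. The block took 0.532% of all TPM in the sensitive strain and 1.75% in the resistant one.

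**Figure D1:**
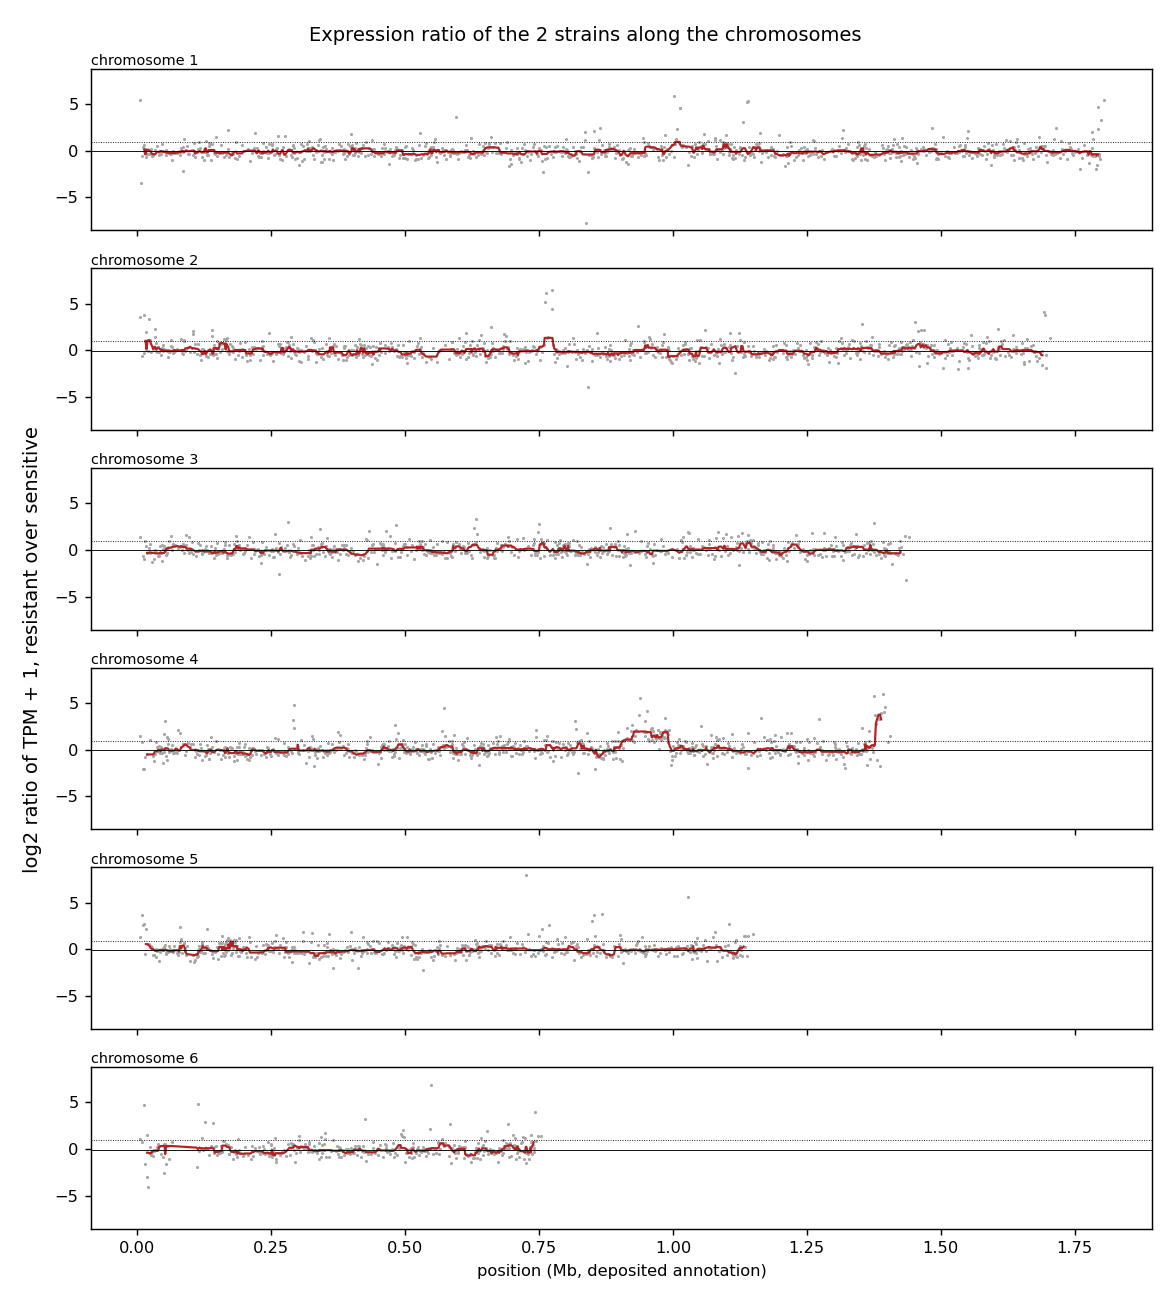
The log2 ratio of TPM + 1, resistant over sensitive (vertical axis), against gene position in Mb on the 6 chromosomes (horizontal axis), with 1 library per strain. Grey points are genes, the red line is the rolling median over 11 genes, the solid line is the median of all genes (-0.07) and the dotted line lies 1 above it; the block of 51 genes stands above the dotted line on chromosome 4.

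Whole chromosomes differed little. The median log2 ratio was -0.13 on chromosome 1, -0.11 on chromosome 2, -0.02 on chromosome 3, 0.02 on chromosome 4, -0.07 on chromosome 5 and -0.11 on chromosome 6. Chromosome 4 held 114 of the genes at least 2-fold higher, of which 43 lay in the block. In 10000 random gene orders the longest run had 11 genes, against the 51 seen.

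Inside the block, among genes with a named product, those with the highest TPM in the resistant strain were a mitochondrial 60S ribosomal protein (MP87_02953, 255 against 1213), a ferric reductase (MP87_02943, 69.9 against 919) and a purine nucleoside permease (MP87_02947, 83.1 against 718). An ATP12 domain protein (MP87_02967) was at 253 against 620, the translocation protein sec72 (MP87_02966) at 286 against 562 and the homoserine dehydrogenase hom6 (MP87_02950) at 219 against 483. The cytochrome P450 gene (MP87_02948, 949,247 to 950,869, plus strand, no intron) was at 150 against 553, a ratio of 3.68 (interval 3.51 to 3.85). The erg4 erg24 ergosterol biosynthesis gene (MP87_02952, 957,786 to 959,354, minus strand, no intron) was at 193 against 542, a ratio of 2.81 (interval 2.69 to 2.93). Genes of the erg4 and erg24 family encode sterol reductases late in the pathway. The azole target belongs to the cytochrome P450 superfamily, but the annotation names this gene only by that superfamily.

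Of the ferric reductases of the block, MP87_02943 had a ratio of 13.1 (interval 12.3 to 14.1), and its neighbour MP87_02944 was at 0.61 against 73.4, a ratio of 120.3 (interval 50.9 to 369) that rests on 5 reads in the sensitive library and was the highest in the block. A hypothetical gene, MP87_02949, had a ratio between theirs, at 29.7 against 521. The lowest ratio in the block was that of an AP-2 complex subunit sigma gene (MP87_02963, 121 against 123). MP87_02949 and MP87_02963 were named after their values were seen. The first gene of the block, the mitochondrial elongation factor mef2 (MP87_02929), was at 43.9 against 82.8, and the last, MP87_02979, at 5.98 against 20.7. The edges were set by a rolling median and carry an error of a few genes: the next gene to the right, a TPR-like protein (MP87_02980), was at 141 against 587, and the one after it, a CNDP dipeptidase (MP87_02981), at 476 against 434. The annotation holds the block once, since 3 of its 29 distinct named products recur elsewhere and never in a stretch of more than 2 genes, so reads from all copies would be counted on the same gene models.

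**Figure D2:**
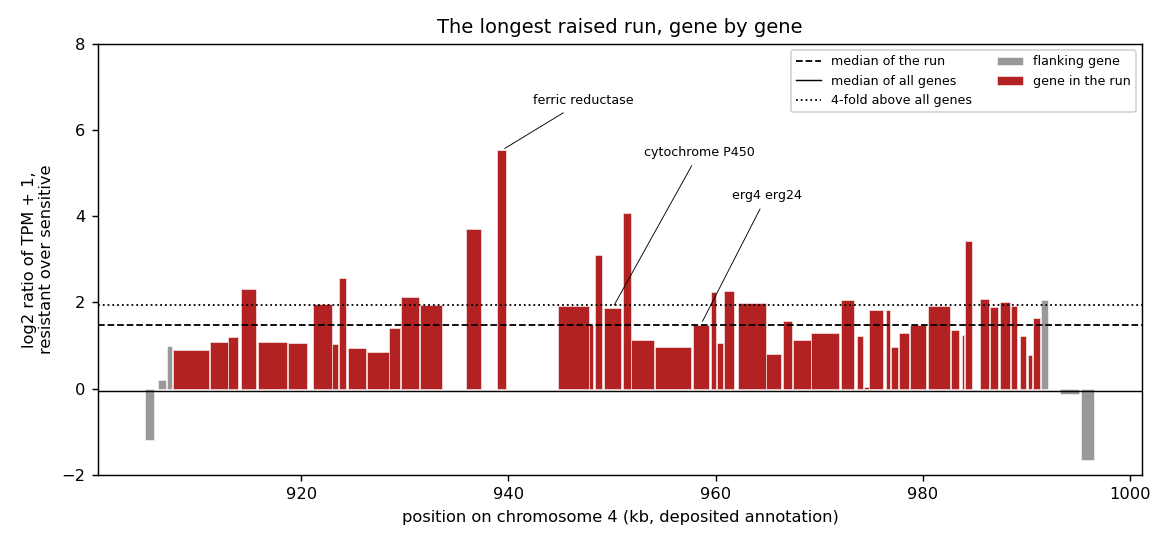
The log2 ratio of TPM + 1, resistant over sensitive (vertical axis), of each gene of the block and of 3 flanking genes on each side, drawn to scale against position in kb on chromosome 4 (horizontal axis), with 1 library per strain. Red bars are genes of the block and grey bars flanking genes; the dashed line is the block's median (1.48), the solid line the median of all genes (-0.07) and the dotted line 4-fold above it.

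The other raised runs were short. A run of 6 genes on chromosome 2 (760,293 to 775,484) holds 3 secretory lipases and the thioredoxin-like gene MP87_01272, and a run of 5 genes near the right end of chromosome 4 (1,377,857 to 1,389,183) opens with the fet3 gene MP87_03190. In the run of 6 genes, MP87_01267, MP87_01268 and MP87_01271 had 0, 2 and 0 reads in the sensitive library. The limit on genes near 0 therefore applies to that run. Runs of 3 genes and of 1 gene lay near the left end of chromosome 2. A run of at least 6 genes also came up in 416 of the 10000 random orders, so by length these short runs are less set apart than the block. By height the order differed: the highest rolling median was 3.74 in the run of 5 genes and 1.94 in the block. Relative to the median of all genes, the highest rolling median seen was 3.81, against at most 2.38 in the random orders. No lowered run was found.

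Ergosterol genes outside the block were mostly slightly lower in the resistant strain. Of 23 measured members of the pathway, 1 was at least 2-fold higher (the block gene MP87_02952), 2 were at least 2-fold lower and 20 were under 2-fold apart. No member has a product named as the azole target, as mevalonate kinase or as farnesyl diphosphate synthase, so these counts do not cover those enzymes. The 2 lower ones were diphosphomevalonate decarboxylase (MP87_00578, 92.0 against 38.3, 2.40-fold lower, interval 2.16 to 2.68), of the mevalonate pathway, and lanosterol synthase (MP87_00679, 106 against 50.2, 2.11-fold lower, interval 1.96 to 2.28), which closes the sterol rings. The median of the list was -0.32 (quartiles -0.50 and 0.09), at the 2.06 percentile of 10000 random lists matched on expression, and without the block gene it was -0.32 at the 2.19 percentile. Under median-of-ratios scaling lanosterol synthase came just inside 2-fold.

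Among the early enzymes, acetyl-CoA acetyltransferase (MP87_03271) was at 277 against 144, hydroxymethylglutaryl-CoA synthase (MP87_01808) at 331 against 249, and hydroxymethylglutaryl-CoA reductase (MP87_03697), the main control point of the mevalonate pathway, at 55.8 in both. Phosphomevalonate kinase (MP87_01758) was at 63.1 against 86.7 and isopentenyl diphosphate isomerase (MP87_02622) at 124 against 142. Farnesyl-diphosphate farnesyltransferase (MP87_03138) was at 121 against 83.3, a phytoene/squalene synthetase (MP87_03398) at 60.1 against 47.8 and squalene monooxygenase (MP87_02029), the terbinafine target, at 84.6 against 62.4. Of the late enzymes, the sterol C-methyltransferase (MP87_01847) was at 466 against 434, erg25 (MP87_01673) at 291 against 209, the C-3 sterol dehydrogenase (MP87_03916) at 244 against 212, erg28 (MP87_00573) at 113 against 142, the C5 desaturase (MP87_02097) at 151 against 149 and the C-22 desaturase (MP87_02203) at 134 against 107. The C-8 sterol isomerase is annotated as neighbouring models (MP87_01485, 204 against 125, and MP87_01486, 95 against 92.1), as is a sterol reductase (MP87_02865, 82.3 against 65.1, and MP87_02866, 33.1 against 54.8). Neighbouring models with the same product can be parts of 1 gene, and their values are then uncertain. Another gene labelled erg4 erg24 (MP87_00396, chromosome 1) was at 126 against 78.8, opposite in direction to the gene of that label in the block. No sequence was compared, so whether they encode the same enzyme was not tested. The NADPH-cytochrome P450 oxidoreductase (MP87_00551), which feeds electrons to P450 enzymes, was at 127 against 160.

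The only sterol regulator with a named product was the SREBP cleavage-activating protein (MP87_03840), a sterol sensor, at 18.4 against 15.4. After the values were seen, the 5 genes annotated as cytochrome P450 were also compared. Outside the block they were at 433 against 681 (MP87_00061), 41.2 against 20.2 (MP87_00062), 36.2 against 21.6 (MP87_01136) and 128 against 182 (MP87_01137), so the block gene had the highest ratio of the 5.

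The genes listed as drug efflux transporters were not higher as a group. The list, matched by product words, includes some that are not drug pumps by name. Examples are the regulator ssz1 (MP87_01823), a mitochondrial ABC transporter (MP87_00085) and an exporter of a-factor (MP87_03069). Of 17 members 0 were at least 2-fold higher and 1 was at least 2-fold lower, an MFS multidrug transporter (MP87_03152, 42.9 against 10.2, 4.2-fold lower, interval 3.54 to 5.0). The pleiotropic drug resistance ABC transporters MP87_02390 and MP87_02391, of the family that pumps azoles out of other yeasts, were at 317 against 212 and 41.3 against 25.9. A multidrug pheromone exporter (MP87_03068) had the highest ratio of the list, 38.6 against 65.8. It is the neighbour, on the same strand, of the a-factor exporter MP87_03069, which was at 16.42 against 14.55. Whether these are parts of 1 gene, and whether MP87_03068 is a drug pump, was not tested. The list's median was -0.23, at the 20.4 percentile of its random lists.

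Iron and copper uptake genes held the highest median of the lists fixed beforehand, 0.86 (quartiles -0.32 and 3.24), at the 99.9 percentile of its random lists. Of 11 members, 5 were at least 2-fold higher, 1 was at least 2-fold lower and 5 were under 2-fold apart. Besides the ferric reductases of the block, a high-affinity iron transporter (MP87_03189, chromosome 4, 1,376,321 to 1,377,502) was at 8.96 against 132, a ratio of 14.7 (interval 12.0 to 18.3). The adjacent fet3 gene (MP87_03190), which encodes a multicopper ferroxidase, was at 8.41 against 63.5, a ratio of 7.55 (interval 6.38 to 8.98). A CTR copper transporter (MP87_01179) was at 153 against 368, while a second fet3 gene on chromosome 6 (MP87_04105) was at 179 against 81.6; both were named after their values were seen. The 9 members outside the block had a median of 0.83, at the 99.7 percentile. Without the copper transporters, a split made after the values were seen, the 7 members left had a median of -0.19, at the 37.2 percentile. The iron transporter MP87_03189 stayed among these 7. With so few members, leaving out other higher members would also lower the median, so the split does not single out copper.

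Of 22 proteasome genes, 19 lay below the median of all genes, and the list's median of -0.42 (quartiles -0.65 and -0.28) was at the 0.16 percentile of its random lists. Most differences were small: 1 was at least 2-fold lower, the rpn1 subunit (MP87_03723, 212 against 87.5), and 1 at least 2-fold higher, the non-ATPase subunit 12 (MP87_01647, 111 against 247). Subunits of the 20S core were among the lower ones, at 295 against 152 (MP87_00732) and 604 against 324 (MP87_02679). Heat shock and chaperone genes had a median of -0.29 (4.71 percentile), within the central 95% of their random lists, and all 23 were under 2-fold apart. Heat shock protein 60 (MP87_00710), the mitochondrial chaperonin, was at 1810.0 against 978 and a heat shock protein on chromosome 3 (MP87_02095) at 827 against 474, whereas the mitochondrial co-chaperones mge1 (MP87_00108) and MP87_01173 were at 240 against 402 and 58.9 against 105.

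The 67 cytosolic ribosomal protein genes had a median of -0.09, at the 51.6 percentile, with 2 at least 2-fold higher (ribosomal protein S10, MP87_00700, 81.2 against 206, and L4, MP87_03668, 105 against 255) and 65 under 2-fold apart. These 2 higher genes carry no 40S or 60S label in their product, so that they are cytosolic is uncertain. The genes labelled 40S S10 (MP87_03305, 1674 against 2183) and 60S L4 (MP87_00018, 3010 against 2672) were under 2-fold apart. L13 (MP87_03747) was at 2049 against 4038 and L6 (MP87_00302) at 3444 against 1829. Of the 26 mitochondrial ribosomal protein genes, 22 lay above the median of all genes, the median was 0.25 (97.53 percentile) and 2 were at least 2-fold higher: the block gene MP87_02953 and a 30S ribosomal protein S17 (MP87_01971, 67.4 against 272). A 39S protein (MP87_02753) was at 125 against 220 and L36 (MP87_01978) at 189 against 309. The 25 members outside the block had a median of 0.22, at the 96.62 percentile. Members were matched by product words, and that a 50S ribosomal protein L22 of high TPM (MP87_01005, 2934 against 3975) is mitochondrial is uncertain. The difference between the lists was not tested.

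The list of lipid and protein hydrolases, drawn up for the secreted enzymes with which this lipid-dependent yeast feeds on its host, differed in both directions. Its members were matched by product words and include some that are not secreted by name, such as a cytosolic phospholipase (MP87_00701). Of 46 members 12 were at least 2-fold higher, 8 at least 2-fold lower and 26 under 2-fold apart, with a median of 0.21 (98.6 percentile). Neighbouring LIP family lipases on chromosome 1 (MP87_00493 and MP87_00494) were listed at 0 against 22.8 and 22.5, at least 31.8-fold and at least 33.3-fold higher, whereas the LIP family lipase MP87_03766 on chromosome 6 was 18.2-fold lower (interval 15.6 to 21.3). Lipases form a multigene family, and reads that fit several members make these values uncertain. Cell wall genes also differed in both directions, with 5 of 16 at least 2-fold higher, 2 at least 2-fold lower and a median of -0.30 (9.70 percentile). Of the chitin deacetylases, which turn chitin into chitosan, MP87_03762 was at 4.38 against 135 and MP87_03764 at 6.10 against 19.6. The more abundant MP87_03317 was at 293 against 726 and MP87_04103 at 218 against 166; these 2 were named after their values were seen. Of the exo-beta-glucanases near the right end of chromosome 1, MP87_00884 was at 0.47 against 36.1 and MP87_00881 at 104 against 26.2.

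**Figure D3:**
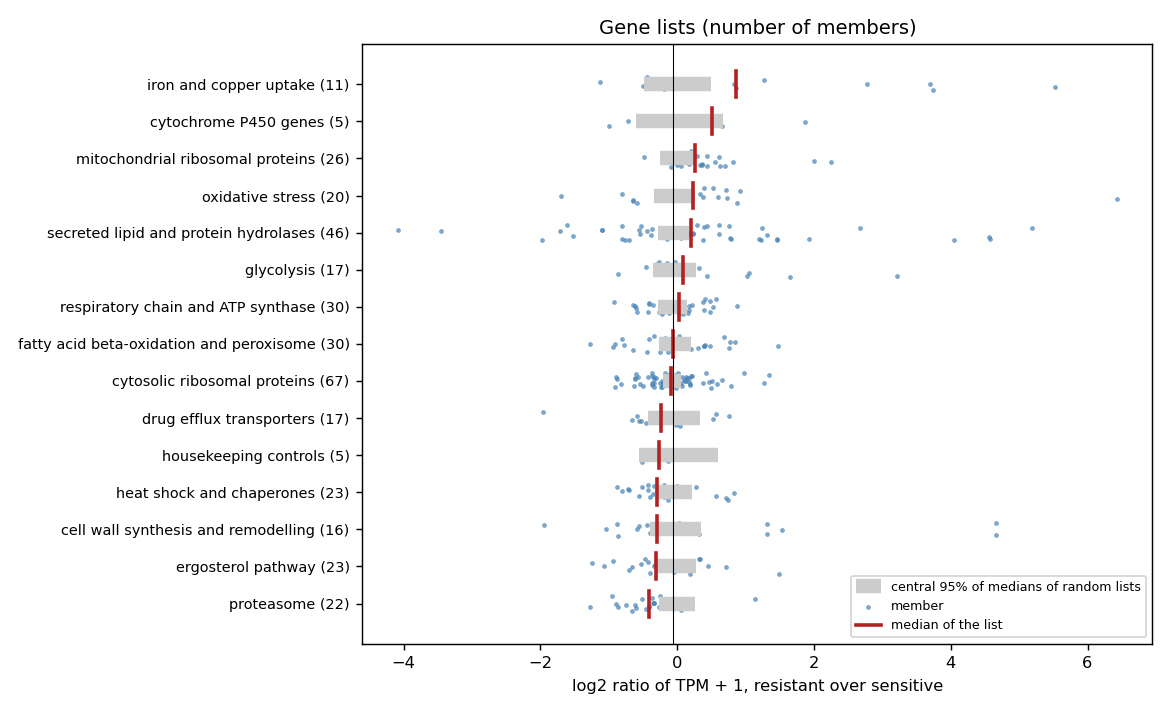
The log2 ratio of TPM + 1, resistant over sensitive (horizontal axis), of the members of each gene list (rows, with the number of members), 1 library per strain. Points are genes, red bars list medians and grey bands the central 95% of medians of 10000 random lists matched on expression; iron and copper uptake lies furthest right (0.86) and the proteasome furthest left (-0.42).

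In glycolysis and fermentation 4 of 17 genes were at least 2-fold higher and 0 lower, with a median of 0.08 (81.2 percentile): an alcohol dehydrogenase (MP87_03131, 17.7 against 174, a ratio of 9.79, interval 8.48 to 11.3), a phosphoglycerate mutase-like protein (MP87_02270, 56.1 against 178), triosephosphate isomerase (MP87_03037, 549 against 1143) and pyruvate decarboxylase (MP87_02293, 161 against 328). Matched by product words, the phosphoglycerate mutase-like gene is of uncertain membership in this list. Pyruvate decarboxylase came just inside 2-fold when the top 1% of genes was left out. All 30 genes of the respiratory chain and ATP synthase were under 2-fold apart, with a median of 0.03 (85.3 percentile) that took the other sign without the top 1% of genes. Examples are cytochrome c oxidase chain VI (MP87_01188, 1437 against 756), an ATP synthase epsilon subunit (MP87_00591, 496 against 317), a 12 kDa NADH-ubiquinone oxidoreductase subunit (MP87_02607, 728 against 475) and cytochrome c subunit VIb (MP87_02126, 54.6 against 101). The 30 beta-oxidation and peroxisome genes had a median of -0.06 (45.8 percentile), which took the other sign under median-of-ratios scaling. In that list a peroxin (MP87_00279) was at 197 against 80.8, an acetyl-CoA acyltransferase (MP87_00857) at 349 against 182, an enoyl-CoA hydratase (MP87_03856) at 639 against 339 and a peroxisomal membrane protein of the block (MP87_02968) at 148 against 411. Another enoyl-CoA hydratase (MP87_02300), named after its values were seen, was at 533 against 898.

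Oxidative stress genes had a median of 0.23 (96.3 percentile), with 1 of 20 at least 2-fold higher, 1 at least 2-fold lower and 18 under 2-fold apart. The higher one was the thioredoxin-like gene MP87_01272, and the lower one thioredoxin itself (MP87_02774), a disulfide reductant, at 8220 against 2527, 3.25-fold lower (interval 3.17 to 3.34). A catalase-peroxidase (MP87_00492) was at 198 against 377 and a cysteine peroxiredoxin (MP87_02889) at 50.5 against 93.3, while a second catalase-peroxidase (MP87_02433), named after its values were seen, was at 454 against 258. The 5 housekeeping controls were all lower by less than 2-fold, with a median of -0.26 (21.1 percentile): elongation factor 1A (MP87_01989) was at 11273 against 7878, actin (MP87_02897) at 141 against 102, and beta tubulins at 614 against 512 (MP87_00683) and 224 against 200 (MP87_03954).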

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

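No paired analysis was possible because each strain had 1 library, so no replicate could be matched or left out. The settings were fixed before the data were examined, except for the list of cytochrome P450 genes, which was added after. Depth limits genes with few reads in the sensitive library, where a ratio rests on counting error and on the floor of 3 reads. The block on chromosome 4 kept its 51 genes under each pseudocount, filter and scaling and with a window of 7 genes, and grew to 54 genes with a window of 21 and to 55 with a threshold of 0.58, with medians from 1.44 to 1.55. The number of raised runs, 5, came to 3 with a pseudocount of 5, 3 without the top 1% of genes, 14 with a window of 7, 1 with a window of 21 and 31 with a threshold of 0.58, where lowered runs numbered 10 against 0. A lower threshold or narrower window admits more windows by construction. Genes at least 4-fold lower numbered 11 with a pseudocount of 5 against 20, since that pseudocount shrinks ratios of low genes. The counts of genes at least 2-fold higher and lower, 393 and 201, came to 443 and 160 under median-of-ratios scaling, which moved the median of all genes by 0.07. That shift took chromosome medians beyond their intervals over genes, to -0.0589 on chromosome 1, -0.0401 on chromosome 2, 0.0439 on chromosome 3, 0.084 on chromosome 4 and -0.0018 on chromosome 5. List medians stayed within their intervals over members in all 97 values under the alternatives. Of 616 values of named genes, 50 moved beyond counting error and 0 of the 51 genes at least 2-fold apart changed sign, though 2 fell inside 2-fold and 3 others passed it under at least 1 setting. Sums over annotated copies were not run, since the annotation holds the block once, and most lists had fewer than 3 members matched by symbol.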

Other observations

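Genes near chromosome ends differed more often than others. Of 97 genes within 20 kb of the first or last annotated base of a chromosome, 26 (26.8%) were at least 4-fold apart between the strains, against 107 of 4019 elsewhere (2.7%). A family of 17 genes that share the product Malapachy_3699, all within 20 kb of an end, was higher in the resistant strain in 17 of 17 cases, with log2 ratios from 0.77 to 5.42. The 5 members at TPM of at least 10 in the resistant strain sat at both ends of chromosome 1, the left end of chromosome 2 and near the right end of chromosome 4. No sequence was compared, so whether these genes share reads, and with them how certain single values are, was not tested.

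The right end of chromosome 4 held several large differences side by side, chosen here after the values were seen. A hypothetical gene (MP87_03188) was at TPM 13.0 in the sensitive strain against 732 in the resistant one, next to the iron transporter and fet3 genes, and a GPR/FUN34 family protein (MP87_03194) was at 30.1 against 478. Between them a phospholipase C (MP87_03191) was at 136 against 62.4 and a lipase (MP87_03193) at 50.2 against 14.6. The next genes toward the end, MP87_03195, MP87_03196 and MP87_03197, had 0 reads in the sensitive library against 982, 142 and 96. They may be absent from the sensitive strain or diverged there. Among hypothetical genes the highest log2 ratio of TPM + 1, 7.99, was that of MP87_03571 (chromosome 5, 725,517 to 726,023), at 13.3 against 3627, a TPM ratio of 273 (interval 213 to 357), and the lowest, -3.93, that of MP87_01305 (chromosome 2), at 440.0 against 28.0, 15.7-fold lower (interval 14.6 to 17.0).

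The tests below were chosen after the results were seen, except the percentile of the iron and copper uptake genes outside the block, which was planned, though the bounds it was held to were set after. The block on chromosome 4 was higher in the resistant strain. Poorer alignment of the sensitive strain's reads, in a block of ordinary expression, would leave the resistant strain at an ordinary level there. Instead, the block's median TPM in the resistant strain was above that of all 3715 other windows of as many genes. In the sensitive strain it was at the 26.4 percentile. The block was picked by its high ratio, so this does not exclude poorer alignment in a block of high expression. A gene length bias is argued against by random lists matched on coding length, whose highest median was 0.52 against 1.48 for the block. Whether output follows 4 copies in proportion, a log2 ratio of 2 relative to all genes, cannot be told apart from a lower output: the median was 1.55, the upper bound of its 95% order-statistic interval over genes was 1.98, and it was 2.01 with a pseudocount of 0.1. Extra copies remain a hypothesis here, since DNA depth was not used, and the interval over genes is not one over cultures.

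There were 20 genes below TPM 1 in the sensitive strain and at TPM of at least 10 in the resistant one. Lower depth is argued against, since at the resistant strain's TPM the sensitive library would have given a median of 324.2 reads for them, against 1 seen. The reverse set, below 1 in the resistant strain and at least 10 in the sensitive one, had 0 genes, but this decides nothing, since the lowest TPM of any gene in the resistant strain was 1.08. Gene models and an alignment target taken from the resistant strain only, under which genes absent from or diverged in CBS 1879 would read near 0, therefore cannot be told apart from lower expression of genes that both strains carry. The products of 4 of the 20 carry a CBS 1879 locus tag that no other gene carries, which names a best match and does not show that the gene is there.

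Iron and copper uptake genes were higher as a list. Of the 5 members at least 2-fold higher, 3 lie outside the block on chromosome 4, with ratios of 14.7 (MP87_03189), 7.55 (MP87_03190) and 2.41 (MP87_01179). Extra copies of the block would not add copies of these genes. Whether such copies could raise these genes indirectly was not tested, so their values do not decide for or against copies as the account of the pattern. Whether the members outside the block differ as a set cannot be told. The 9 members outside the block were at the 99.68 percentile of their random lists, but the 95% order-statistic interval of their median over members ran from -0.50 to 2.78, and the 7 left without the copper transporters had a median of -0.19, at the 37.17 percentile. Loss of the sensitive strain's reads at chromosome ends cannot be told apart from higher expression for the iron transporter and its fet3 neighbour, which lie within 50 kb of an end. Of the 3 raised members outside the block, 1 lies further in, the copper transporter MP87_01179. A response of the resistant strain to iron may also be at work and was not tested.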
